A study of Homo sapiens with 2 samples.

How the data were processed

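The RNA content of single cells was measured in 2 libraries of human cerebral organoids, three-dimensional cultures of neural tissue grown from H9, an established human embryonic stem cell line. 1 library pooled 8 organoids given vehicle and the other pooled 10 organoids given an ALK inhibitor. Per the labels, treatment began at day 23 in vitro and cells were taken at day 35, which is 12 days later. Droplet libraries were made with a 10x Chromium kit that counts transcripts from their 3′ ends with unique molecular identifiers (UMIs). The deposited files hold the UMI count of each gene in each cell barcode, with no normalization. The values tested as whole numbers, with totals that were not constant over barcodes. Per the submitters' processing notes, the authors used Cell Ranger and the human genome build GRCh38. The Cell Ranger version and the gene annotation are not given in the sources used here.

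The vehicle file held 17906 gene rows and the ALK inhibitor file 18175, and 17616 genes were listed in both. The rows held genes found in at least 11 cells of the vehicle library and at least 12 cells of the ALK inhibitor library, and nearly all ribosomal protein genes were missing from them. Shared genes carried 99.99% of UMIs in each library and were the only ones compared, while 290 genes listed for the vehicle library alone and 559 listed for the ALK inhibitor library alone entered no ratio. Symbols were taken from the files, and 17409 of the shared identifiers were matched in a table of current gene names, so that list members under older symbols were found. Gene positions were taken from GENCODE release 29 on GRCh38, which may not be the annotation the authors used.

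Cells were kept with at least 200 detected genes and at most 10% of UMIs from mitochondrial genes. This removed 7 of 10766 barcodes of the vehicle library and 5 of 12587 of the ALK inhibitor library. The study states 10736 and 12606 cells. Doublets were scored in each library with Scrublet and kept in the main values. Its own threshold marked 16.6% of vehicle cells and 0.0159% of ALK inhibitor cells, so it did not work in the latter library, and cells in the highest 10% of scores of each library are called doublet candidates below.

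Counts of both libraries were joined with no batch correction, scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes were scaled, reduced to 30 principal components and clustered with the Leiden method at resolution 1 on 15 neighbours. A cluster took the name of the marker list with the highest mean log2 ratio of CPM (a gene's UMIs scaled to the library total, with 20 CPM added to both sides) against all other cells. Marker lists covered radial glia, cycling and intermediate progenitors, neurons in general, cortical excitatory and inhibitory neurons, Cajal-Retzius cells, astroglia, oligodendrocyte precursors, choroid plexus, cortical hem, mesenchymal, neural crest, retinal or pigment, muscle, epithelial, pluripotent, endoderm and endothelial cells and microglia. A name needed a mean of at least 0.6 and at least 3 markers past 0.5. Clusters whose best list was neurons in general, cortical excitatory neurons or Cajal-Retzius cells were all named neuron-like. A cluster stayed unnamed when more markers of another class were among its 10 leading genes, when over 33% of its cells were doublet candidates or when over 90% of them came from 1 library. The limits of 0.6, 33% and 90%, the joint neuron name, the doublet candidates and the rule of 1.2-fold in every class used below were set after the data had been seen.

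With 1 library per group there is no replicate and no test. For each gene, UMIs were summed over all kept cells of a library, or over the cells of 1 class, and divided by the total. The log2 ratio of ALK inhibitor over vehicle CPM was given a conditional exact binomial interval of 95%, sums an exact Poisson interval and shares of cells a Clopper-Pearson interval, all of which cover counting error only. Genes at a mean CPM of at least 10 were counted as apart when their ratio was at least 1.5. For gene lists, the median log2 ratio of members at that level was placed among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. Function lists with fewer than 5 such members and marker lists with fewer than 3 received no median. To separate the mix of clusters from levels within clusters, CPM was also averaged over clusters with the same weights in both libraries. This was added after the data had been seen and leaves out clusters with fewer than 100 cells in either library. It does not remove free RNA that cells of 1 cluster release into others.

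The genes named in the text follow a rule of size. It took the 12 highest and the 12 lowest log2 ratios at a mean CPM of at least 20 in the whole libraries, the 4 highest and the 4 lowest at a mean CPM of at least 50 in each of the 3 classes with most cells, up to 4 members with the largest ratios of each function list, and the ALK receptor family with its ligands. Mitochondrial, ribosomal protein and clone-named genes were left out of the ranking, and 2 clone-named genes lay above the last of the 12 highest. Some genes that the rule names are not reported here. Other genes named below were chosen after their values had been seen. For shares of cells with a UMI, each cell was thinned to 2000 UMIs.

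The lists, markers, filters and the rule for named genes, together with the alternatives for cell filters, doublet removal, cluster resolution, genes used for clustering, scaling, expression limits and thinning, were fixed before the data were examined. The steps were tested on simulated counts drawn from the mean profile of both libraries, at their own depths, with 200 genes changed. No unchanged gene of 9382 was 1.5-fold apart by counting error in the whole libraries, and 10 of 9001 were in neuron-like cells. All genes simulated 2-fold apart were found, and of those simulated exactly 1.5-fold apart 59.7% were found in the whole libraries. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.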

Results

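Single-cell transcriptomes of human cerebral organoids at day 35 in vitro were compared between 1 library of 8 pooled organoids given vehicle and 1 library of 10 pooled organoids given an ALK inhibitor 12 days earlier. The labels name neither the compound nor its dose, and do not say which of the receptors abbreviated ALK it acts on. After filtering, 10759 vehicle cells and 12582 ALK inhibitor cells remained, from 10766 and 12587 barcodes and against 10736 and 12606 cells stated for the study. The libraries held 62907847 and 73799399 UMIs, with a median of 4599 UMIs and 2175 genes per vehicle cell and 4724.5 UMIs and 2152.5 genes per ALK inhibitor cell. The median share of mitochondrial UMIs was 1.97% in vehicle cells and 2.5% in ALK inhibitor cells. Each group is 1 library, so no difference below has a replicate check, and the exact 95% intervals of shares, levels and ratios cover counting error only, while those of list medians are order-statistic intervals over members.

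The question the design puts is how the ALK inhibitor alters the cell types and gene expression of the organoids. In the ALK inhibitor library, cells resembling cortical hem, the signalling centre at the medial edge of the cortex, made up a larger share. Cortical excitatory neurons, intermediate progenitors and radial glia-like cells made up smaller shares, although for intermediate progenitors the difference was small at the finer clustering resolution. The radial glia marker SOX2 hardly differed, in 46.9% of vehicle and 45.5% of ALK inhibitor cells thinned to the same depth. The median log2 ratio of radial glia markers was 0.11. SOX2 was found in more cells than the class holds, so it cannot decide on the class. Shares are parts of a whole, so larger hem-like and unnamed shares can by themselves lower the others. Most of the difference in hem-like cells lay in a cluster in which all 8 hem markers stood above their level in other cells but which was led by other genes, among them PAX3 of the midbrain, hindbrain and spinal list. Genes of glycolysis and the hypoxia response, among them the glucose transporter SLC2A1 and the glycolytic enzyme HK2, were higher in the ALK inhibitor library, with a list median above 0 in 16 of the 17 clusters compared. Genes of neuronal differentiation, neurites and synapses were lower in the summed library, whereas with every cluster weighted alike their medians lay near 0. Transcripts of the ALK ligand MDK were higher in the summed libraries, by less with every cluster weighted alike, and those of its relative PTN were at the same level in the summed libraries.

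Clustering gave 18 clusters, of which 14 could be named from markers. Radial glia-like cells, the stem cells of the developing cortex, were 32.9% of vehicle cells [32.0, 33.8] and 23.2% of ALK inhibitor cells [22.5, 24.0], a log2 ratio of shares of -0.50. They came from clusters 2, 3 and 4. The largest part of the class was cluster 2 in the vehicle library with 41.8% of it, and cluster 3 in the ALK inhibitor library with 41.3%. Of all cells, cluster 2 was 13.7% and 6.34%, cluster 4 was 9.61% and 7.30%, and cluster 3 was 9.54% and 9.58%, so the lower share of the class lay in clusters 2 and 4. Cluster 4 was led by genes of DNA replication such as RRM2 and GINS2. Neuron-like cells were 19.4% [18.6, 20.1] and 11.5% [10.9, 12.0], a log2 ratio of -0.76. Their cluster 1, led by the cortical excitatory transcription factors NEUROD6 and NEUROD2, was 16.4% of vehicle cells and 7.22% of ALK inhibitor cells. Their cluster 12, led by LHX1 and by RELN, the extracellular protein secreted by Cajal-Retzius neurons, was 2.98% and 4.25%, and so made up 15.4% of the class in the vehicle library and 37.1% in the ALK inhibitor library. Intermediate progenitor-like cells, the neurogenic daughters of radial glia marked by EOMES, were 4.52% [4.13, 4.93] and 2.61% [2.34, 2.90], a log2 ratio of -0.79 that ranged from -1.13 at resolution 0.5 to -0.12 at resolution 2. Over the alternatives for cells and clustering, the log2 ratio ranged from -0.92 to -0.34 for radial glia-like and from -0.75 to -0.38 for neuron-like cells.

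Cortical hem-like cells were 8.03% of vehicle cells [7.52, 8.56] and 18.5% of ALK inhibitor cells [17.8, 19.2], a log2 ratio of 1.2 [1.09, 1.32], which ranged from 0.95 at resolution 2 to 2.06 with called doublets removed. The class joins cluster 10, led by the Wnt agonists RSPO2 and RSPO1, and cluster 5, led by CBLN1, SPARCL1, ZIC1 and PAX3. Cluster 10 held most of the class in the vehicle library and was 4.91% of vehicle and 6.26% of ALK inhibitor cells, whereas cluster 5 held most in the ALK inhibitor library and was 3.12% and 12.2%. Cluster 5 contained none of the hem markers among its 10 leading genes, although the hem genes WLS and WNT2B reached 341 and 88.8 CPM there in the ALK inhibitor library against 89.8 and 8.49 CPM outside the class. PAX3, a dorsal neural tube transcription factor that the lists place with midbrain, hindbrain and spinal identity, stood at 129 CPM in cluster 5 of the vehicle library and 131 CPM in that of the ALK inhibitor library, against 1.33 and 7.15 CPM in cluster 10. In the ALK inhibitor library, WLS and WNT2B stood at 318 and 26.9 CPM in cluster 10, below their levels in cluster 5. RSPO2 and RSPO1 stood at 140 and 48.8 CPM in cluster 5, against 474 and 114 CPM in cluster 10. EMX2, a dorsal telencephalic transcription factor, was at 268 CPM in cluster 5 and 521 CPM in cluster 10, against 459 CPM outside the class. The hem name is thus less sure for cluster 5, which holds most of the difference in share. Of hem-like cells, 23.1% in the vehicle library and 18.8% in the ALK inhibitor library were doublet candidates.

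Choroid plexus-like cells, the epithelium that secretes cerebrospinal fluid, were 15.4% [14.8, 16.1] and 16.3% [15.7, 17.0], a log2 ratio of 0.08 [-0.01, 0.18] that ranged from -0.27 to 0.26 over the alternatives for cells and clustering. Cluster 7 held most of them in the vehicle library with 54.8% of the class. Cluster 6, led by AQP1 and by hypoxia genes such as ANKRD37 and ADM, held most in the ALK inhibitor library with 51.7%. Cycling progenitor-like cells were 8.25% [7.74, 8.79] and 8.17% [7.70, 8.66], within counting error in the main clustering. But their log2 ratio ran down to -0.30 at resolution 0.5 and lay outside the main interval in 6 of 9 alternatives. The class leaves out cluster 4, led by genes of DNA replication and counted as radial glia-like, at 9.61% and 7.30%. Inhibitory neuron-like cells were 1.81% [1.57, 2.08] and 2.33% [2.07, 2.61], a log2 ratio of 0.36 that was 1.94 with called doublets removed and 1.49 with doublet candidates removed, and 3 alternatives formed no such class. Unnamed clusters held 9.71% of vehicle cells and 17.4% of ALK inhibitor cells. Among these, clusters 8 and 16, rich in doublet candidates, were 5.73% and 1.59% of vehicle and 6.35% and 2.51% of ALK inhibitor cells. Cluster 11, led by the stress genes CRYAB, GDF15 and DDIT3, was 2.36% and 6.33%. Cluster 18 held 3 vehicle and 274 ALK inhibitor cells and was left unnamed because nearly all its cells came from 1 library.

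Because some cluster-defining genes differed between the libraries, cells were also clustered without the genes at least 1.5-fold apart. The log2 ratio of shares was then 1.33 for hem-like, -0.62 for neuron-like, -0.54 for intermediate progenitor-like and -0.34 for radial glia-like cells, and -0.27 for choroid plexus-like cells, whose direction turned. No inhibitory neuron-like cluster was formed there.

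**Figure D1:**
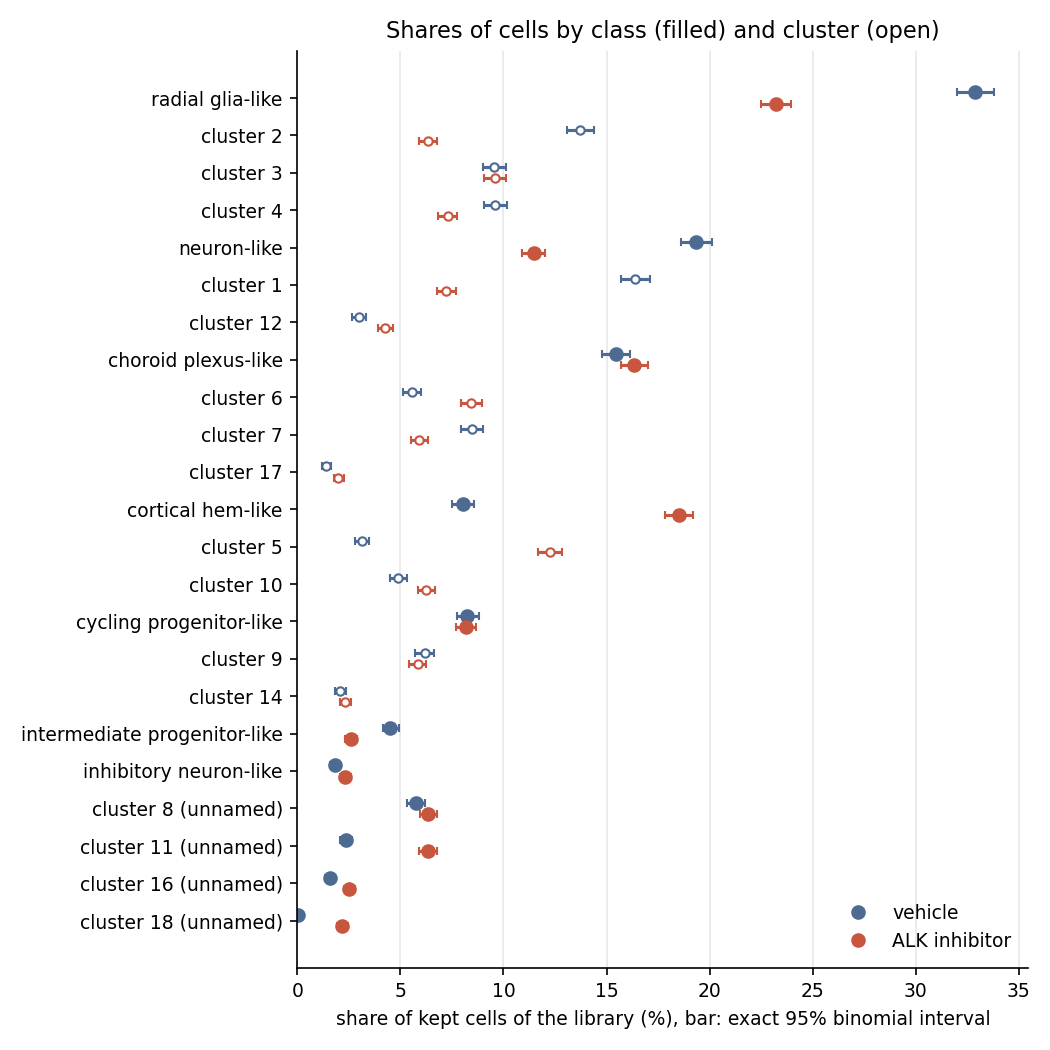
Share of kept cells in each class (filled points) and in each cluster of classes with several clusters (open points), in percent of each library, with exact 95% binomial intervals as bars. Cortical hem-like cells lie at 8.03% in the vehicle library and 18.5% in the ALK inhibitor library, and neuron-like cells at 19.4% and 11.5%.

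Summed over all kept cells, 177 of 9380 measured genes were at least 1.5-fold higher and 56 at least 1.5-fold lower in the ALK inhibitor library. With every cluster weighted alike, 59 were higher and 32 lower, and 52 of the 177 and 24 of the 56 were still at least 1.5-fold apart. The highest ratio belonged to AIF1 (ENSG00000204472, chromosome 6, 31615184 to 31617021 on GRCh38), known as a microglial and macrophage protein, with 7.54 CPM [6.88, 8.25] in the vehicle library and 49.9 CPM [48.3, 51.5] in the ALK inhibitor library, a log2 ratio of 2.73 [2.59, 2.87]. AIF1 also led cluster 11 and kept a log2 ratio of 1.75 with clusters weighted alike. The synaptic organiser CBLN1, the matrix-associated protein SPARCL1 and the zinc-finger transcription factors ZIC1 and ZIC4 had log2 ratios of 1.87, 1.43, 1.37 and 1.32. These 4 genes lead cluster 5, whose share differed as above, and with clusters weighted alike they were 0.64, -0.16, 0.40 and 0.37. CBLN1 stood at 215 and 301 CPM within cluster 5 and at 6.77 and 16.5 CPM in cells outside the hem-like class. ZIC1 stood at 296 and 322 CPM in cluster 5 and at 23.1 and 46.6 CPM outside the class. Such levels outside the class can come from free RNA of cluster 5, so these weighted ratios need not be differences within clusters. The melanosome protein PMEL, a leading gene of cluster 11, had a log2 ratio of 1.69, and 0.61 weighted.

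Among the other genes on the higher side, CEBPD had the lowest ratio with clusters weighted alike. SLC2A1 (ENSG00000117394, chromosome 1, 42925375 to 42959176) stood at 108 CPM in the vehicle and 261 CPM in the ALK inhibitor library, a log2 ratio of 1.28 [1.24, 1.32] against 0.98 weighted. The hypoxia-induced genes ANKRD37, BHLHE40 and STC2 had log2 ratios of 1.31, 1.45 and 1.15, against 0.82, 0.97 and 0.80 weighted. LHX9, a LIM-homeodomain transcription factor, had 12.9 and 29.5 CPM, a log2 ratio of 1.2 [1.08, 1.31] against 1.24 weighted. The transcription factor CEBPD had a log2 ratio of 1.22, against 0.37 weighted.

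On the lower side, NEUROD6 (ENSG00000164600, chromosome 7, 31337461 to 31340894) stood at 427 CPM in the vehicle and 217 CPM in the ALK inhibitor library, a log2 ratio of -0.98 [-1.0, -0.95]. NEUROD2, the acetylcholine-hydrolysing enzyme BCHE and the synaptic kinase-like protein CAMKV had log2 ratios of -0.94, -0.91 and -0.84. All 4 lead cluster 1, and with clusters weighted alike they were -0.38, -0.38, -0.49 and -0.32. That weighting does not remove free RNA of cluster 1 from other clusters. RTN1, a reticulon of neuronal endoplasmic reticulum, and TMEM158 had log2 ratios of -0.76 and -0.73, against -0.47 and -0.59 weighted. Also among the 12 lowest were the LIM-domain factor LMO3 at -0.97, the actin-related gene ACTR3B at -0.93, the transcription factor subunit gene TAF9B at -0.84, C8orf4 at -0.87, the neuropeptide gene CCK at -0.81 and NR2E1, a nuclear receptor of neural stem cells, at -0.79. Their weighted log2 ratios were -0.89, -0.79, -0.65, -0.79, -0.84 and -0.67.

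**Figure D2:**
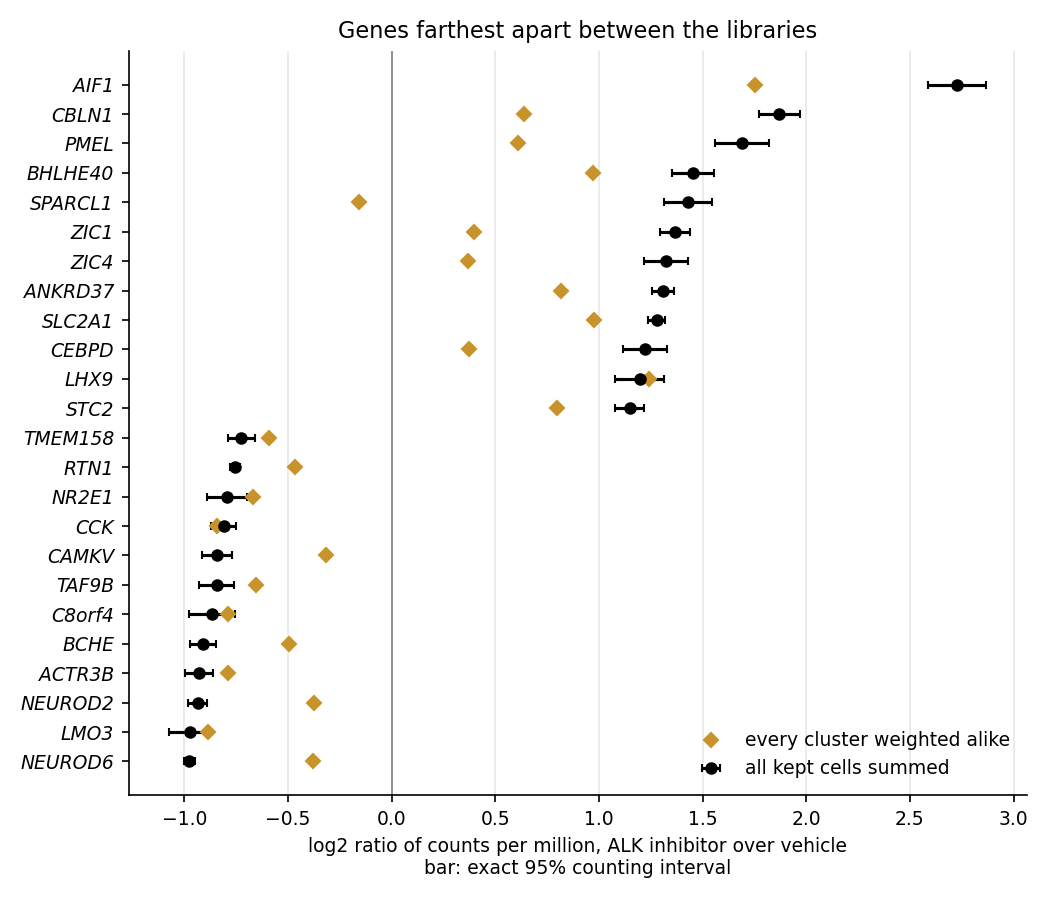
Log2 ratio of CPM, ALK inhibitor over vehicle, for the 12 highest and 12 lowest genes of the whole libraries, with exact 95% counting intervals (black), and with every cluster weighted alike (diamonds). AIF1 lies at 2.73 and 1.75, while SPARCL1 goes from 1.43 to -0.16.

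Among the function lists, glycolysis and hypoxia stood farthest from 0. All 25 measured members were above a ratio of 1 and 11 were at least 1.5-fold higher in the ALK inhibitor library. The median log2 ratio was 0.50 [0.36, 0.76], at percentile 100 of random lists, and 0.42 [0.26, 0.60] with clusters weighted alike, again at percentile 100. Besides SLC2A1 and ANKRD37, HK2 had 42.7 and 81.4 CPM, a log2 ratio of 0.93, and NDRG1, a hypoxia-induced differentiation gene, had 8.51 and 16.5 CPM, a log2 ratio of 0.95 against 0.54 weighted. Within classes the median was 0.59 in intermediate progenitor-like, 0.57 in cycling progenitor-like, 0.53 in choroid plexus-like, 0.50 in hem-like, 0.48 in radial glia-like, 0.38 in inhibitory neuron-like and 0.26 in neuron-like cells. With the clusters of the class weighted alike it was 0.31 in choroid plexus-like cells, where 3 instead of 10 members were at least 1.5-fold higher. By cluster it ran from 0.17 in cluster 1 to 0.68 in cluster 4, apart from cluster 17, which is choroid plexus-like, at -0.02. All 13 mitochondrial genes were also higher in the ALK inhibitor library, with log2 ratios from 0.12 to 1.05, beside the median mitochondrial shares of 1.97% and 2.5%, and the nuclear transcript MALAT1 was higher in 17 of 17 clusters.

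**Figure D3:**
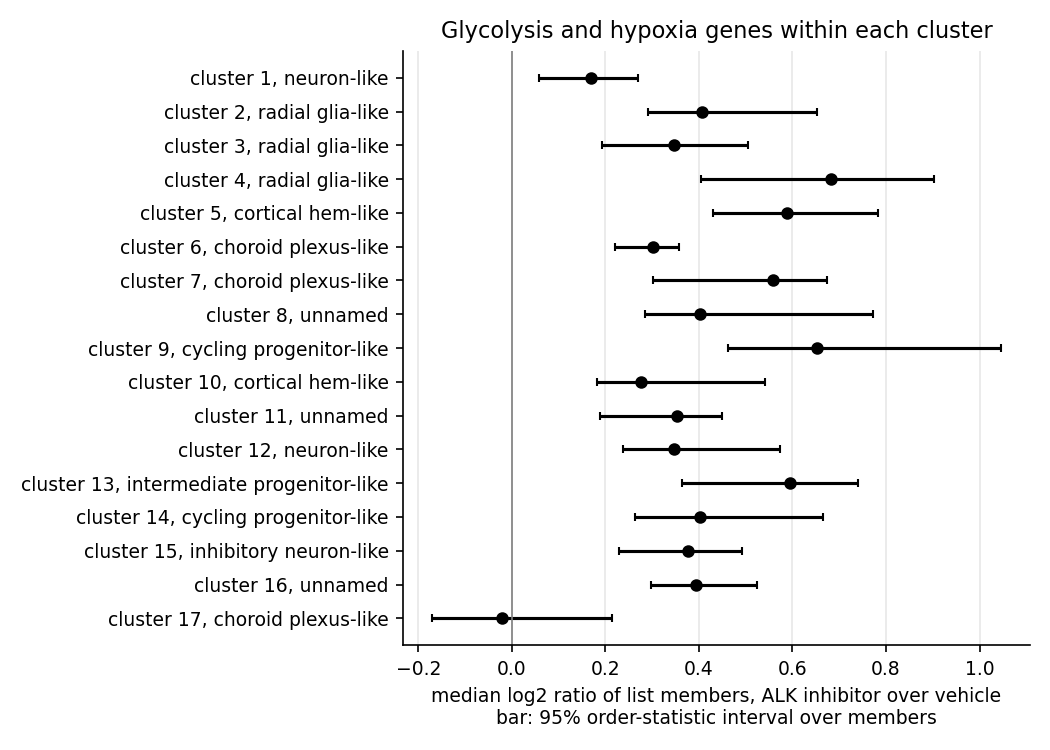
Median log2 ratio of CPM, ALK inhibitor over vehicle, of the glycolysis and hypoxia genes within each cluster, with 95% order-statistic intervals over members. Cluster 4 lies highest at 0.68, and cluster 17 lies at -0.02 with an interval that spans 0.

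Lists of neuronal genes were lower in the summed ALK inhibitor library. Proneural and neuronal differentiation factors had a median log2 ratio of -0.25 (percentile 0), with 16 of 21 members below a ratio of 1. Neurite and cytoskeleton genes had -0.25 (percentile 0) and synapse genes -0.24 (percentile 0.01), among them the vesicle fusion protein SNAP25 at -0.70 and the glutamate receptor subunits GRIA1 at -0.57, GRIA2 at -0.50 and the synaptic regulator CPLX2 at -0.51. With every cluster weighted alike the medians of the 3 lists were -0.04, 0.02 and -0.09, so that the neurite list turned its direction, and SNAP25, GRIA1, GRIA2 and CPLX2 had -0.45, -0.32, -0.19 and -0.082. Against most of their lists, the POU factor POU3F2 and the neurofilament gene NEFL were higher, with log2 ratios of 0.60 and 0.93, against 0.26 and 0.15 weighted, while NSG1 and CRMP1 were at -0.52 and -0.40, against -0.25 and -0.14 weighted.

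The Wnt list had a median log2 ratio of 0.32 (percentile 100), led by the ligand WNT2B at 0.88, the agonist RSPO3 at 0.85, the feedback gene AXIN2 at 0.69 and the ligand transporter WLS at 0.56. Weighted alike the median was 0.01 (percentile 76.7), where RSPO3 alone of these 4 stayed high at 0.67. ERK pathway output had a median of 0.25 (percentile 100), against 0.14 weighted (percentile 99.97), with the feedback inhibitors SPRY1 at 1.02 and DUSP6 at 0.68, IER3 at 0.67 and the cyclin CCND1 at 0.44, against 0.61, 0.40, 0.55 and 0.18 weighted. S-phase genes were lower, with 34 of 35 members below a ratio of 1 and a median of -0.21 (percentile 0), against -0.12 weighted (percentile 0.485). UHRF1, CDCA7, GINS2 and DSCC1, which act in DNA replication and chromatin maintenance, had log2 ratios of -0.57, -0.33, -0.32 and -0.30, against -0.37, -0.17, -0.14 and -0.21 weighted. G2 and M phase genes had a median of -0.06 (percentile 19.0), with TTK at -0.47, LBR at -0.39, DLGAP5 at -0.38 and NDC80 at -0.32.

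Smaller medians were found for TGF-beta and BMP response at 0.15 (percentile 99.4), Notch at 0.14 (percentile 98.9), axon guidance and cell adhesion at 0.11 (percentile 99.2), extracellular matrix at 0.23 (percentile 99.7), forebrain regional identity at 0.19 (percentile 99.9) and interferon response at 0.17 (percentile 99.0). With every cluster weighted alike these medians were 0.10, 0.12, 0.13, 0.095, 0.12 and -0.022, so that the interferon list turned its direction. The BMP-induced genes ID1, MSX2 and BAMBI had log2 ratios of 0.68, 0.84 and 0.44, against 0.48, 0.30 and 0.15 weighted, while ID4 had -0.45. The Notch receptors NOTCH3 and NOTCH2 and their targets HES1 and HEY2 lay between 0.38 and 0.42, and NOTCH2 was at 0.22 weighted. The guidance genes SEMA3C, EFNA5 and SLIT2 had 1.34, 0.86 and 0.76, against 0.41, 0.70 and 0.54 weighted, and the receptor EPHA5 had -0.76, against -0.38. In the matrix list COL6A2, SPARC, COL6A1 and COL4A2 had 0.47, 0.42, 0.25 and 0.23, against 0.13, 0.040, 0.095 and 0.34 weighted. In the forebrain list OTX1 and LMX1A had 0.58 and 0.53, against 0.35 and 0.17. The antigen-presenting gene HLA-B had 0.67, and IFI27 and ISG15 had 0.44 and 0.26, against 0.23, 0.18 and 0.031 weighted.

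ER and integrated stress response genes had a median of 0.03 (percentile 89.7), although DDIT4, a hypoxia- and stress-induced inhibitor of mTOR, had 221 and 477 CPM, a log2 ratio of 1.11. ATF3, DDIT3 and CHAC1 had 0.58, 0.52 and 0.41, against 0.027, 0.19 and 0.40 weighted. p53 response and apoptosis had a median of -0.04 (percentile 48.2) and -0.17 weighted (percentile 0.12), with PMAIP1 and BCL2 at 0.45 and 0.31, against 0.17 and 0.10 weighted, and BAX and BCL2L1 both at -0.22. Immediate early and heat shock genes had -0.01 (percentile 64.0), with FOSB and FOS at 0.77 and 0.29 and HSPA6 and HSPH1 at -0.59 and -0.28, where FOS was at 0.17 and HSPA6 at -1.21 weighted. Cholesterol synthesis genes had -0.05 (percentile 45.6) and 0.036 weighted (percentile 97.0), with IDI1, SQLE and MVK at -0.22, -0.17 and -0.17 and LSS at 0.18. The receptors of the TGF-beta family that carry ALK numbers, the Hedgehog pathway and the midbrain, hindbrain and spinal list had 4, 2 and 2 measured members, too few for a median.

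**Figure D4:**
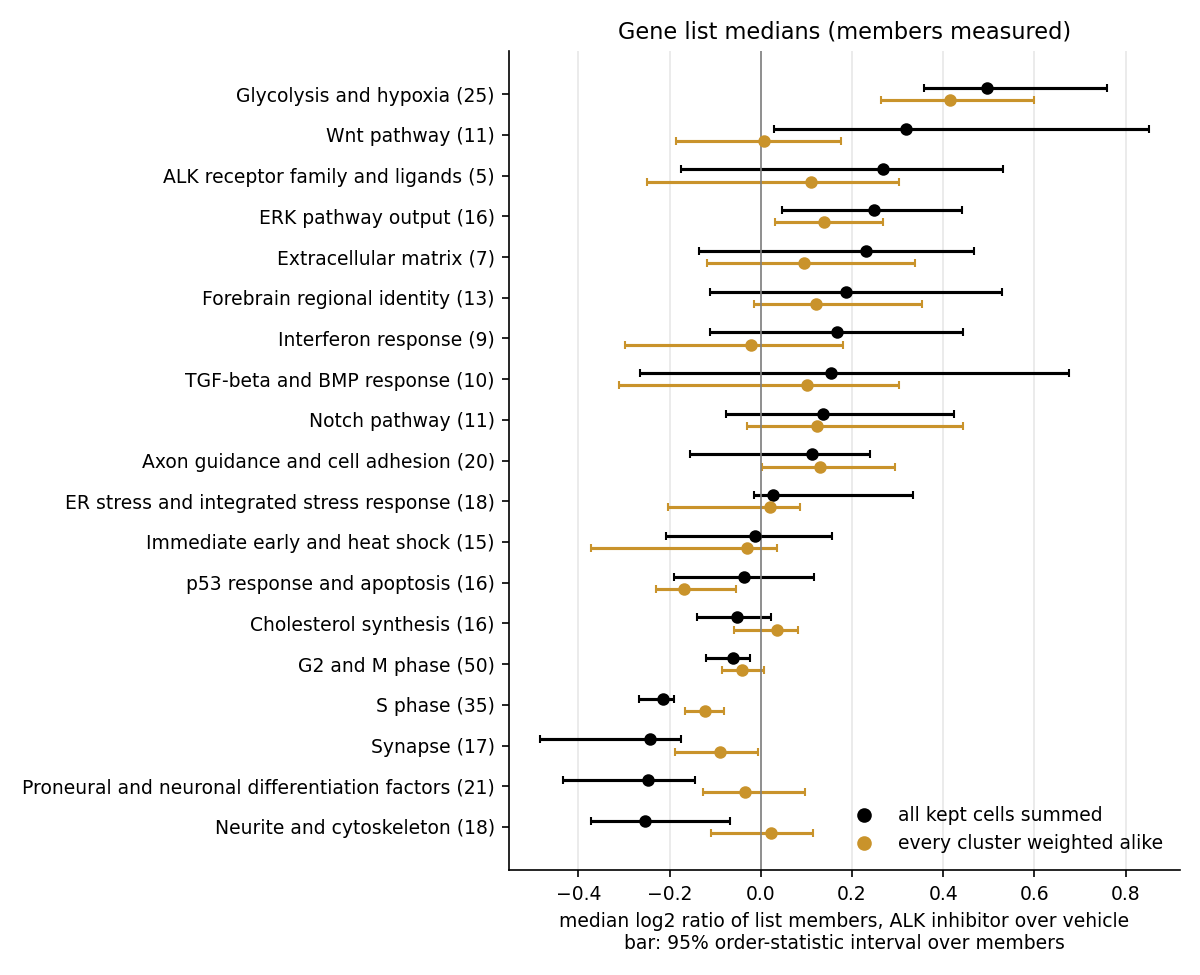
Median log2 ratio of CPM, ALK inhibitor over vehicle, of each function list with all kept cells summed (black) and with every cluster weighted alike (gold), with 95% order-statistic intervals over members, whose number stands in brackets. Glycolysis and hypoxia lies at 0.50 and 0.42, and the Wnt list goes from 0.32 to 0.01.

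Of the list for the receptor ALK and its ligands, ALK and the related LTK were not analysed here. MDK (ENSG00000110492, chromosome 11, 46380756 to 46383837), a heparin-binding growth factor reported as an ALK ligand, had 426 CPM [421, 431] in the vehicle and 616 CPM [610, 622] in the ALK inhibitor library, a log2 ratio of 0.53 [0.51, 0.55]. Its log2 ratio was 1.01 in neuron-like cells, 0.48 in cycling progenitor-like, 0.27 in radial glia-like and 0.05 in choroid plexus-like cells. With clusters weighted alike it was 0.11 in the whole libraries, 0.62 in neuron-like and 0.17 in choroid plexus-like cells. PTN had 352 and 354 CPM, a log2 ratio of 0.01 [-0.02, 0.03], and -0.25 with clusters weighted alike. The coreceptors LRP1 and SDC3 had log2 ratios of 0.35 and 0.27, and the receptor phosphatase PTPRZ1 had -0.17, which turned to 0.03 with clusters weighted alike. The ALK-activating cytokine genes listed as FAM150A and FAM150B stood at 1.34 and 0.366 CPM in the vehicle and 1.42 and 0.447 CPM in the ALK inhibitor library, not detectably apart at this depth.

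Within radial glia-like cells 134 of 8965 genes were at least 1.5-fold higher and 83 lower in the ALK inhibitor library, and with median-of-ratios scaling the split was 169 against 56. The highest were the secreted glycoprotein STC2, SLC2A1, the chemokine receptor CXCR4 and RSPO3, with log2 ratios of 1.45, 1.40, 1.24 and 1.22. Clustering without cell cycle genes gave SLC2A1 a log2 ratio of 0.92 here. RSPO3 stood at 108 CPM in the vehicle and 251 CPM in the ALK inhibitor library in this class. The lowest were NEUROD6, ACTR3B, the neuropeptide gene PMCH and TAF9B, with -1.11, -1.10, -1.02 and -0.89. NEUROD6 stood at 81.8 and 37.9 CPM here and at 54.2 and 34.2 CPM in choroid plexus-like cells, against 1752 and 1188 CPM in neuron-like cells, so its value in radial glia-like cells is at a level that free RNA can give.

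Within choroid plexus-like cells 150 of 8804 genes were at least 1.5-fold higher and 108 lower, and 98 and 105 with the clusters of the class weighted alike. The highest were DLK1, a Notch-related ligand, with 92.4 and 311 CPM and a log2 ratio of 1.75, then BHLHE40, DDIT4 and ANKRD37 with 1.26, 1.23 and 1.22, against 0.89, 0.89 and 0.75 with the clusters of the class weighted alike. The lowest were the EGF receptor inhibitor ERRFI1, the hormone-like gene PTHLH, the chemokine CCL2 and CCK, with -1.23, -1.10, -0.99 and -0.98. These depended on the cells of the class. With doublet candidates removed ERRFI1, CCL2 and CCK were at -0.16, -0.23 and -0.37 and PTHLH at -1.13, and clustering without cell cycle genes left CCL2 at -0.0057. Within neuron-like cells 249 of 9016 genes were higher and 82 lower. The counts were 108 and 69 with its clusters weighted alike, and cluster 12 made up more of the class in the ALK inhibitor library. Among the highest, DLK1, the antisense transcript LHX5-AS1 and CXCR4 had log2 ratios of 1.78, 1.77 and 1.73, against 0.94, 0.79 and 1.24 with its clusters weighted alike. PMCH, LMO3, BCHE and CDKAL1 had -1.27, -1.18, -0.83 and -0.81. BCHE was at -0.49 with its clusters weighted alike. PMCH was at -0.67 with doublet candidates removed, and at -0.44 under the alternative that left it nearest to 0. CDKAL1 turned to 0.01 at the finer clustering resolution of 2.

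Cells with at least 1 UMI of a marker were counted after thinning to 2000 UMIs, which left out 13 vehicle and 10 ALK inhibitor cells. For markers of neurons and hem these shares differed in the direction of the class shares. For the radial glia marker SOX2 they differed little, while the radial glia-like share was lower in the ALK inhibitor library. NEUROD2 was found in 19.0% [18.3, 19.8] of vehicle and 11.5% [10.9, 12.0] of ALK inhibitor cells, against a background of 3.56% and 2.73% in choroid plexus-like cells. DCX, a microtubule protein of young neurons, was found in 33.7% and 28.1%, against 15% and 15.1%. WLS was found in 12.3% [11.7, 13.0] and 19.7% [19.0, 20.4], against 3.94% and 4.78% in neuron-like cells, and RELN in 2.04% and 3.32%, against 0.785% and 0.781% in choroid plexus-like cells. EOMES was in 3.11% and 2.71% against 0.302% and 0.390%, and GAD2, the GABA-synthesising enzyme, in 1.28% and 1.73% against 0.483% and 0.488%, both with choroid plexus-like cells as background. With neuron-like cells as background, SOX2 was in 46.9% and 45.5% against 9.61% and 9.22%, and the proliferation marker MKI67 in 7.62% and 8.04% against 1.34% and 0.901%. The choroid plexus transcript TTR was in 99.3% and 97.7% of all cells and in 99.3% and 97.1% of neuron-like cells, which is background.

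Before thinning, the shares in vehicle and ALK inhibitor cells were 30.2% and 20.2% for NEUROD2, 53% and 46.6% for DCX, 24.8% and 37.1% for WLS, 4.77% and 7.24% for RELN, 6.36% and 5.88% for EOMES, 2.78% and 3.62% for GAD2, 68.6% and 69.4% for SOX2, 15.7% and 16.5% for MKI67 and 100% and 99.96% for TTR. Median depths among these cells were 4600 and 4727.5 UMIs in all cells of the thinned set, 4054 and 3912 UMIs in neuron-like cells and 6834 and 5338 UMIs in choroid plexus-like cells.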

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

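The tests below of the mix of clusters, of free RNA, of differences between the pools, of doublets and of single organoids were chosen only after the results had been seen.

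Some genes were listed for 1 library alone and so entered no comparison, yet carried at least 100 UMIs there. The midbrain and hindbrain homeobox gene EN2 had 119 UMIs in 104 cells of the ALK inhibitor library, 36.1% of them in cluster 18, which held 2.18% of its cells. HELT, a midbrain neuronal transcription factor, had 105 UMIs in the ALK inhibitor library, with 33 of them in cluster 18. The matrix proteoglycan gene EPYC had 122 UMIs there, 91.0% of them in cluster 5, and TFAP2D, an AP-2 transcription factor, had 120 UMIs, with 42 in cluster 12. The clone-named gene LA16c-380H5.6 had 102 UMIs in the vehicle library, 90.2% of them in cluster 11, but in only 12 cells. A gene not listed for a library can still have UMIs in fewer than 11 vehicle cells or fewer than 12 ALK inhibitor cells, so no value of 0 is claimed.

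Glycolysis and hypoxia genes were higher in the ALK inhibitor library, with a median log2 ratio of 0.50, as were all 13 mitochondrial genes, with median mitochondrial shares of 1.97% and 2.5%, and MALAT1 in 17 of 17 clusters. A different mix of clusters would leave a median near 0 once every cluster is weighted alike, but it was 0.42 [0.26, 0.60]. This argues against the mix alone as the cause, apart from free RNA that a changed mix could carry between clusters. Free RNA from other cells would not raise the cluster with the highest level of the list, and there, in cluster 3, the median was 0.35 [0.19, 0.51]. But cluster 3, which is radial glia-like, was chosen on the sum over members, and single members can stand higher elsewhere. ANKRD37 was at 160 and 371 CPM in choroid plexus-like cells, against 64.6 and 160 CPM in all cells. Free RNA could raise such members in cluster 3, so this test cannot decide on it. The inhibitor and any other difference between the pools, such as organoid size or oxygen supply, cannot be told apart with 1 library per group. A response of the cells to the inhibitor may be the cause and stays an untested hypothesis beside it.

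Cortical hem-like cells were a larger share and neuron-like cells a smaller share of the ALK inhibitor library, with most of the former difference in cluster 5, led by CBLN1, PAX3 and other genes that are not hem markers, at 3.12% and 12.2% against 4.91% and 6.26% for cluster 10. Doublets would bring the log2 ratio of hem-like shares near 0 when doublet candidates are removed, but it was 1.39 [1.26, 1.53], with -0.60 for neuron-like cells. Clustering on genes that differ between the libraries would do so when those genes are left out. But the log2 ratio was then 1.33 [1.21, 1.46], with -0.62 for neuron-like cells. Both tests argue against a cause in the doublet candidates or in genes at least 1.5-fold apart. Candidates were the highest 10% of scores in each library, so an excess of doublets in 1 library could remain. Smaller gene differences also stayed in the clustering. A few organoids rich in hem tissue cannot be told apart from an effect on all of them, since the 18 organoids were pooled with no map from cells to organoids. An effect of the inhibitor on regional fate or on neuron production is consistent with the shares but was not tested.

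Apart from the hypoxia list, 52 genes were at least 1.2-fold higher and 31 at least 1.2-fold lower in all 7 classes, among them the hypoxia-induced genes STC2, DDIT4, HILPDA, STC1 and SLC16A3 outside that list, the splicing factor gene SON and the mitochondrial gene MT-ND3 on the higher side and YWHAQ, CD81 and TAF9B on the lower. A gain of short transcripts in library preparation could give such a uniform shift. Of the higher genes, 30.8% [18.7, 45.1] lay among the 10% of genes with the shortest transcripts, against 3 of the 31 lower genes. The median log2 ratio of all genes in that group was -0.01 against -0.05 for the others. These values argue against it as the whole cause, but the share of higher genes lies above 10%, so a part of it stays open. Free RNA alone, with no shift in the class with a gene's highest level, would leave that class near a log2 ratio of 0. For the 111 genes at least 1.2-fold apart the same way in all other classes, the median there, in the direction of the others, was 0.38 [0.36, 0.42]. This argues against free RNA alone from the 7 classes. But a shift in the class with the highest level could also reach the others as free RNA, and this test cannot tell that apart. Unnamed clusters, 9.71% of vehicle and 17.4% of ALK inhibitor cells, were left out of this test, so free RNA from them stays open. A difference in handling between the 2 libraries stays open beside a response shared by all classes, which may be the cause but has no test here.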

How the results depend on the processing

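The alternatives that remove doublet candidates, cluster without genes 1.5-fold apart, weight clusters alike or leave out unnamed clusters were chosen after the data had been seen. No paired analysis was possible because each group has 1 library and the result comes from no test. Under the alternatives fixed beforehand, 144 values of list medians stayed within their interval and 2 moved, and the glycolysis and hypoxia median lay between 0.40 and 0.52 under all alternatives. Of the ratios of named genes in the whole libraries, 526 stayed within their counting interval under those alternatives and 56 moved, and none whose interval lay on 1 side of 0 turned. Ratios of named genes within classes were less stable, with 156 within their interval, 83 moved and 1 turned. Neuron-like, intermediate progenitor-like and radial glia-like shares were lower, and hem-like shares higher, in the ALK inhibitor library under every alternative, with moved values below. Stricter or looser limits on CPM or ratio count fewer or more genes by construction. Weighting clusters alike removes the difference in their shares, but not free RNA carried between them. Otherwise, where a value moved, the cause was not tested. Depth limits small classes: in simulated counts 10 unchanged genes were 1.5-fold apart in neuron-like cells and 0 in the whole libraries, and counts for classes with fewer cells are not given.

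Log2 ratios of shares follow. With all barcodes they were -0.70 for radial glia-like, -0.029 for choroid plexus-like, -0.65 for neuron-like, -0.21 for cycling and 0.64 for inhibitory neuron-like cells. The stricter cell filter gave -0.39 for radial glia-like and -0.24 for cycling cells. Without cell cycle genes in clustering they were -0.92 for radial glia-like, -0.25 for choroid plexus-like, -0.58 for neuron-like, -0.22 for cycling and -0.43 for intermediate progenitor-like cells. Without genes 1.5-fold apart they were -0.34 for radial glia-like, -0.27 for choroid plexus-like, -0.62 for neuron-like, 1.33 for hem-like, -0.15 for cycling and -0.54 for intermediate progenitor-like cells. With called doublets removed, 16.6% of vehicle and 5.93% of ALK inhibitor cells, they were 0.26 for choroid plexus-like, 2.06 for hem-like and 1.94 for inhibitory neuron-like cells. With doublet candidates removed they were 0.21 for choroid plexus-like, -0.60 for neuron-like, 1.39 for hem-like, -0.15 for cycling, -0.52 for intermediate progenitor-like and 1.49 for inhibitory neuron-like cells. At resolution 0.5 they were -0.21 for choroid plexus-like, -0.38 for neuron-like, 1.82 for hem-like, -0.30 for cycling and -1.13 for intermediate progenitor-like cells. At resolution 2 they were -0.59 for neuron-like, 0.95 for hem-like and -0.12 for intermediate progenitor-like cells. Centred within library, they were -0.16 for choroid plexus-like and -0.56 for neuron-like cells. No inhibitory neuron-like class was formed under the stricter filter, at resolution 0.5 or without genes 1.5-fold apart.

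Counts of genes at least 1.5-fold apart in the whole libraries were 59 higher and 32 lower with clusters weighted alike, 44 and 12 at a mean CPM of at least 50, 485 and 152 at a mean CPM of at least 2, and 41 and 2 at a ratio of at least 2. In radial glia-like cells, 87 were higher with all barcodes and 74 without cell cycle genes. In choroid plexus-like cells, 98 were higher with clusters weighted alike, and lower were 207 under the stricter filter, 71 with doublets removed, 63 at resolution 0.5, 67 without cell cycle genes, 66 centred within library and 68 without genes 1.5-fold apart. In neuron-like cells, 108 were higher with clusters weighted alike and 383 without genes 1.5-fold apart, and lower were 128 without cell cycle genes and 141 without genes 1.5-fold apart.

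With clusters weighted alike, list medians were 0.0074 for Wnt, -0.12 for S phase, -0.035 for proneural factors, 0.022 for neurite genes, which reversed, -0.088 for synapse and 0.036 for cholesterol synthesis. The S phase median was -0.19 with median-of-ratios scaling and the extracellular matrix median 0.56 at a mean CPM of at least 2. SPARCL1 reversed to -0.16 and PTPRZ1 to 0.032 with clusters weighted alike, and CDKAL1 in neuron-like cells to 0.014 at resolution 2.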

Other observations

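The values below, apart from the medians of marker lists in the summed libraries, were chosen after the results had been seen. The regional genes EMX2 and LHX9, and DLK1, differed between the libraries in most clusters, in values from which free RNA was not removed. EMX2, a transcription factor of the dorsal and caudal telencephalon, was higher in the ALK inhibitor library in 17 of 17 clusters, with log2 ratios from 0.17 to 0.81 and an interval above 0 in 16. LHX9 was higher in 17 of 17, with log2 ratios from 0.34 to 2.04 and an interval above 0 in 13. It reached 133 CPM in cluster 12 of the ALK inhibitor library against 36.8 CPM in that of the vehicle library. Its highest ratio, in cluster 4, stood on 3.38 CPM in the vehicle and 13.9 CPM in the ALK inhibitor library. Free RNA can give such low levels, so they need not be differences within the cluster. DLK1 was higher in 15 clusters, most in choroid plexus-like cluster 7 with 83.0 CPM in the vehicle and 503 CPM in the ALK inhibitor library, and lower in clusters 5 and 11.

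Markers of Cajal-Retzius cells, early neurons that arise in part from the cortical hem, had a median log2 ratio of 0.79 in the summed libraries. With clusters weighted alike it was 0.59 over 5 measured members, and both medians stood at percentile 100. Free RNA was not removed from the weighted value, so it need not be a difference within clusters. Markers of the cortical hem had 0.53, against 0.01 weighted, and those of cortical excitatory neurons -0.45, against -0.11 weighted. Markers of choroid plexus had -0.26, of intermediate progenitors -0.27, of neurons in general -0.26, of radial glia 0.11 and of cycling progenitors -0.015, against -0.061, -0.058, 0.041, 0.051 and -0.0024 weighted. Inhibitory neuron and epithelial markers, each with 3 measured members, had 0.55 and 0.26, against 0.28 and 0.031 weighted. The other marker lists had fewer than 3 measured members and received no median.

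Cluster 18, with 274 ALK inhibitor cells and 3 vehicle cells, was set apart from other cells of its library by FAM19A4 at 134 against 4.56 CPM, the Iroquois transcription factor IRX3 at 99.3 against 3.28 CPM and CNPY1, a gene known from the midbrain-hindbrain boundary, at 59.3 against 2.25 CPM. Its doublet candidates were 0.730% of the cells. In the whole libraries, PAX7, a dorsal midbrain and neural tube factor, was at 0.302 CPM in the vehicle and 2.43 CPM in the ALK inhibitor library. PAX3 was at 8.43 and 30.9 CPM. Of its UMIs, 323 and 1444 lay in cluster 5, at 129 and 131 CPM, and 202 and 798 outside the hem-like class. Levels of these 2 genes in cluster 18 alone are not given here.

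Among mitochondrial genes the log2 ratio was lowest for MT-CO1 at 0.12 and highest for MT-ND6 at 1.05, and MT-ND3 stood at 679 and 1127 CPM. Across clusters, log2 ratios ran from 0.15 to 0.49 for MALAT1, and SON was higher in 17 of 17 clusters, from 0.32 to 0.62. Of 7263 genes measured in every class, 62 were at least 1.2-fold higher in all 7 classes, 10 of them from the glycolysis and hypoxia list, of which 23 could be compared. Of barcode sequences, 210 were found in both libraries.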
